A study of Mus musculus with 3 samples.

How the data were processed

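Ribosomal RNA-depleted total RNA of the cytosolic fraction of Lipid A-stimulated mouse BMDM was measured in 3 libraries of 1 group, made from 1 µg of RNA with fragments of 250 to 400 nt, per the labels' protocols. For each library the authors deposited a gene table, a transcript table of the same layout (called the first transcript table here) and a further transcript table (the second). The files use mm10 with GENCODE release M21, per the deposited readme files. The gene table and first transcript table have the column layout of RSEM and derive from transcriptome alignments. The second has the layout of kallisto and derives from the reads and an index, per the deposited readme files. The names and versions of the aligner and quantifiers, and whether counting used the strand, are not given in the sources used here. Reads of a gene and its antisense or overlapping partner can therefore not be told apart with certainty.

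The deposited expected counts are estimated reads per gene or transcript, not normalized, with multi-mapping reads shared out by the authors' estimator. The deposited TPM values divide counts by effective length and scale each library to the same total over all rows, so that short abundant RNAs lower the TPM of messenger RNAs. The deposited percent column gives each transcript's share of its gene's TPM, and isoform shares were computed from the transcript TPM. The deposited columns of effective length and posterior spread of the counts were read to judge shared reads. Gene tables held 81881 rows, of which 55536 matched genes of the annotation (GENCODE M21, Ensembl release 96, GRCm38, the same build as mm10). The other 26345 rows were 26248 tRNA rows, 96 ERCC spike-in rows and 1 phiX174 row. They were left out of library sizes and tests; tRNA and ERCC rows held 0 counts in each library. First transcript tables had 168207 rows and second ones 141864, and gene values of the second were sums over transcripts.

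Genes received 23403552, 50435201 and 35785896 expected counts in replicates 1, 2 and 3. The 95% Wilson intervals of the shares of counts reached at most 0.0146 percentage points to either side. A count of 0, which allows 3 counts, corresponds to 0.128, 0.0595 and 0.0838 CPM in replicates 1, 2 and 3. These limits are on library totals, without the TMM factor used for other CPM values. Intervals and these limits cover counting error only, since reads without molecular identifiers are not independent molecules. The deeper replicate 2 gives the smallest counting error.

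Levels are TPM as deposited, with mean ± SD over libraries. For a list, the median over members of log2(TPM + 1) was taken in each library; with a pseudocount of 1, differences of low genes are understated. Lists were compared within libraries with an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25. List medians were set against 10000 random lists of the same size from genes at 1 TPM or more. For variation between libraries, expected counts were rounded to whole numbers and tested per gene with a chi-square index of dispersion against Poisson sampling, using TMM-scaled library sizes, a mean count of 10 or more and Benjamini-Hochberg adjustment at 0.05. edgeR 4.0.16 in R 4.3.3 gave TMM factors and common and tagwise dispersions from an intercept-only design, and DESeq2 1.42.0 gave alternative size factors and gene-wise dispersions. Deviations of a library from the mean of a gene were taken on log2 CPM of the rounded counts plus a prior count of 0.5. List dispersions and deviations were compared with 10000 lists matched in 20 bins of expression. There is 1 group, so no differential expression was tested. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

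The 26 gene lists, the main tests and the alternatives, except the scale relative to nuclear protein-coding genes, were fixed before the data were examined. They covered the early, late, feedback and interferon responses, NF-kB and TLR4 signalling, macrophage identity and activation, metabolism, proliferation, histones, translation, mitochondria, non-coding RNA classes and 7 other cell types. The rule for named genes was fixed at the same time: the 10 highest nuclear protein-coding genes; per list the 3 highest members (2 for other cell types) and, in 5 response lists, the lowest; the 5 most dispersed genes that passed the between-library test with a mean count of 100 or more; and the 3 genes that differed most between transcript tables among those at 10 TPM or more in one. Genes with near-identical copies are named as uncertain. The values of 1 gene that the rule names are not reported here. Tnf and Fos deviations were drawn from genes named by this rule. Alternatives were other pseudocounts, filters and scalings, DESeq2, the second transcript table, list means and leaving out each library.

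The methods were tested on simulated data. With Poisson counts at the real means and library sizes of 13237 genes and 200 changed genes, the chi-square test recovered 84.0% of genes changed 1.5-fold and 84.0% of those changed 2-fold, and 4.55% of its calls were unchanged genes. Of 200 random lists, 2.5% reached the top 2.5% of dispersion, and their median percentile was 48.1. edgeR returned a common BCV of 10.0% and 25.0% from counts simulated at 10% and 25%. The correction for GC content and length used in the closing section returned -0.01 and 0.31 for simulated list shifts of 0 and 0.3 over a trend fitted on 9619 genes. That simulated trend was linear in GC content and log2 length, which the correction includes, so a trend of another shape was not tested.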

Results

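Bone-marrow-derived macrophages (BMDM), primary macrophages grown from the bone marrow of C57BL/6J mice, were stimulated for 30 min with 100 ng/ml Lipid A, the lipid part of bacterial lipopolysaccharide that activates Toll-like receptor 4 (TLR4). Total RNA of the cytoplasmic fraction was sequenced after removal of ribosomal RNA. The series holds 1 group of 3 libraries, named here replicates 1, 2 and 3 as in the labels. The labels call them biological replicates and give all 3 the same donor record, so errors measure the spread between these samples, which may be partly technical. Genes received 23403552 expected counts in replicate 1, 50435201 in replicate 2 and 35785896 in replicate 3. Neither unstimulated cells nor a nuclear fraction were analysed here, so the values are levels at 1 time point and no gene is called induced or enriched.

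The most abundant messenger RNAs were those of iron storage and the lysosome. The ferritin light and heavy chain genes Ftl1 and Fth1 had 8631 ± 1190 and 8219 ± 1754 TPM (mean ± SD, n = 3, here and below), a unit scaled by transcript length and library total. Lyz2, which encodes lysozyme (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321 in mm10), had 5224 ± 793 TPM. The saposin precursor gene Psap had 4756 ± 627 TPM, and the lysosomal proteases Ctsd and Ctsb had 3959 ± 739 and 2584 ± 469 TPM. Selenop, encoding a selenium transport protein, had 2821 ± 752 TPM, and the membrane glycoprotein gene Gpnmb 2619 ± 747 TPM. Apoe, a lipid carrier gene, and Tmsb4x, encoding an actin-binding peptide, completed the 10 highest nuclear protein-coding genes at 2065 ± 528 and 2053 ± 349 TPM. In all, 10033 genes had a mean of 1 TPM or more, of which 9403 were nuclear protein-coding, and 9439 genes reached 1 TPM in every library.

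Small structured RNAs took most of the TPM of each library. The list of RNA components of the signal recognition particle, 7SK, RNase P, RNase MRP and similar particles held 70.6 ± 6.29% of the TPM but 11.3 ± 3.20% of the expected counts, because TPM divides by length. Nuclear protein-coding genes held 27.0 ± 6.46% of the TPM and 86.7 ± 3.52% of the counts. The signal recognition particle RNA genes Rn7s2 and Rn7s1 had 287110 ± 33031 and 286040 ± 32244 TPM, and the 7SK gene Rn7sk 71894 ± 5652 TPM. Rn7s1 and Rn7s2 are near-identical copies, so the division of reads between them is uncertain. Nuclear protein-coding genes held 34.4% of the TPM in replicate 2, against 22.3% in replicate 1 and 24.3% in replicate 3. Differences between libraries were therefore tested on counts and are given in TMM-scaled CPM, a unit of counts scaled by library total and a TMM factor. Where another unit is named, it applies instead.

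**Figure D1:**
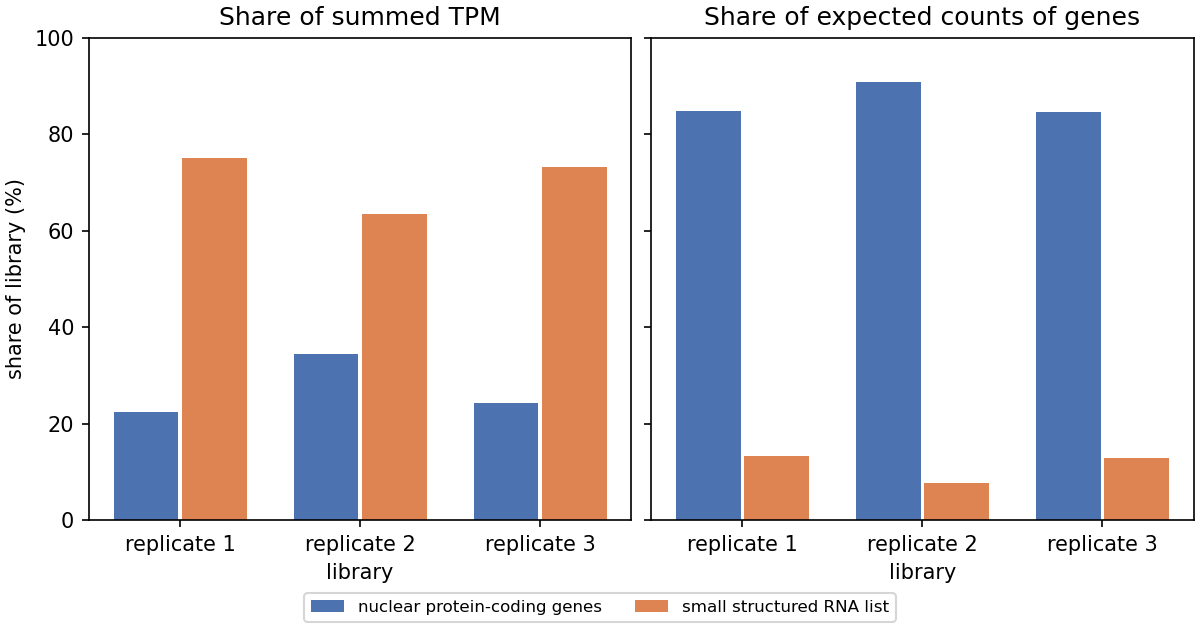
Shares of each library (%, y axis) held by nuclear protein-coding genes and by the small structured RNA list, with summed TPM on the left and summed expected counts on the right, with 1 bar per library and gene class. Structured RNAs hold 63.4% to 75.1% of the TPM but 7.57% to 13.3% of the counts.

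Whether genes of the early response to TLR4 ligands stood above genes of the late response after 30 min was asked with lists of known members. Transcripts of immediate-early transcription factors were abundant: all 13 measured members had a mean of 1 TPM or more and 8 had 100 TPM or more. Fos, encoding a subunit of AP-1 (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273), had 570 ± 246 TPM, the zinc-finger factor gene Egr1 had 341 ± 17.5 TPM and the AP-1 gene Junb 327 ± 36.9 TPM. Myc was the lowest member, at 4.43 ± 1.16 TPM. Of 12 primary cytokine and chemokine genes, 10 had 10 TPM or more. The highest were Tnf, encoding tumour necrosis factor (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), at 420 ± 145 TPM, and the chemokine genes Cxcl2 at 257 ± 64.2 TPM and Ccl3 at 257 ± 56.3 TPM. The chemokine gene Cxcl3 was lowest, at 0.210 ± 0.0361 TPM.

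All 20 genes for negative-feedback regulators of NF-kB, MAP kinases and mRNA stability had 1 TPM or more, and 11 had 100 TPM or more. Zfp36, which encodes an mRNA-destabilising protein (ENSMUSG00000044786.6, chromosome 7, 28376784 to 28380253), had 558 ± 26.5 TPM. Nfkbia, the gene of the NF-kB inhibitor IkB-alpha, had 437 ± 81.1 TPM, and Ppp1r15a, encoding a phosphatase subunit of the stress response, 415 ± 238 TPM. Nfkbie, another NF-kB inhibitor gene, was the lowest member at 6.00 ± 1.69 TPM. Late-response genes were low: 10 of 15 had less than 1 TPM. Of the 5 exceptions, the highest were the anti-inflammatory cytokine gene Il10 (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974) at 38.8 ± 8.27 TPM, the cytokine subunit gene Ebi3 at 21.9 ± 5.32 TPM and the acute-phase gene Saa3 at 8.76 ± 2.59 TPM. Il12a had 0 counts in each library. On library totals without a TMM factor, this allows up to 0.128 CPM in replicate 1, 0.0595 CPM in replicate 2 and 0.0838 CPM in replicate 3. Of the interferon-stimulated genes, all 19 had 1 TPM or more but none reached 100 TPM. Ifit2 had 87.7 ± 24.3 TPM and Ifit3 82.1 ± 27.6 TPM, while Mx2 was lowest at 2.77 ± 0.320 TPM.

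As medians over list members of log2(TPM + 1), the levels were 7.14 ± 0.24 for the immediate-early, 6.33 ± 0.19 for the cytokine and 6.69 ± 0.21 for the feedback list. The late-response list had 0.40 ± 0.15 and the interferon-stimulated list 4.44 ± 0.41. Within libraries, the immediate-early list lay 6.75 ± 0.23 above the late-response list, the cytokine list 5.94 ± 0.09 and the feedback list 6.29 ± 0.09. The same 3 lists lay 2.70 ± 0.27, 1.89 ± 0.35 and 2.25 ± 0.32 above the interferon-stimulated list. All 6 differences had the same sign in 3 of 3 libraries. The two-sided exact sign-flip permutation test gave p = 0.25 for each, which is the smallest p that 3 libraries allow (n = 3). The sizes depended on scale: the differences from the late-response list ranged from 3.89 to 8.44 over the alternatives tried, and the gap between the cytokine and interferon-stimulated lists was 0.61 in TMM-scaled CPM, which does not divide by length.

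**Figure D2:**
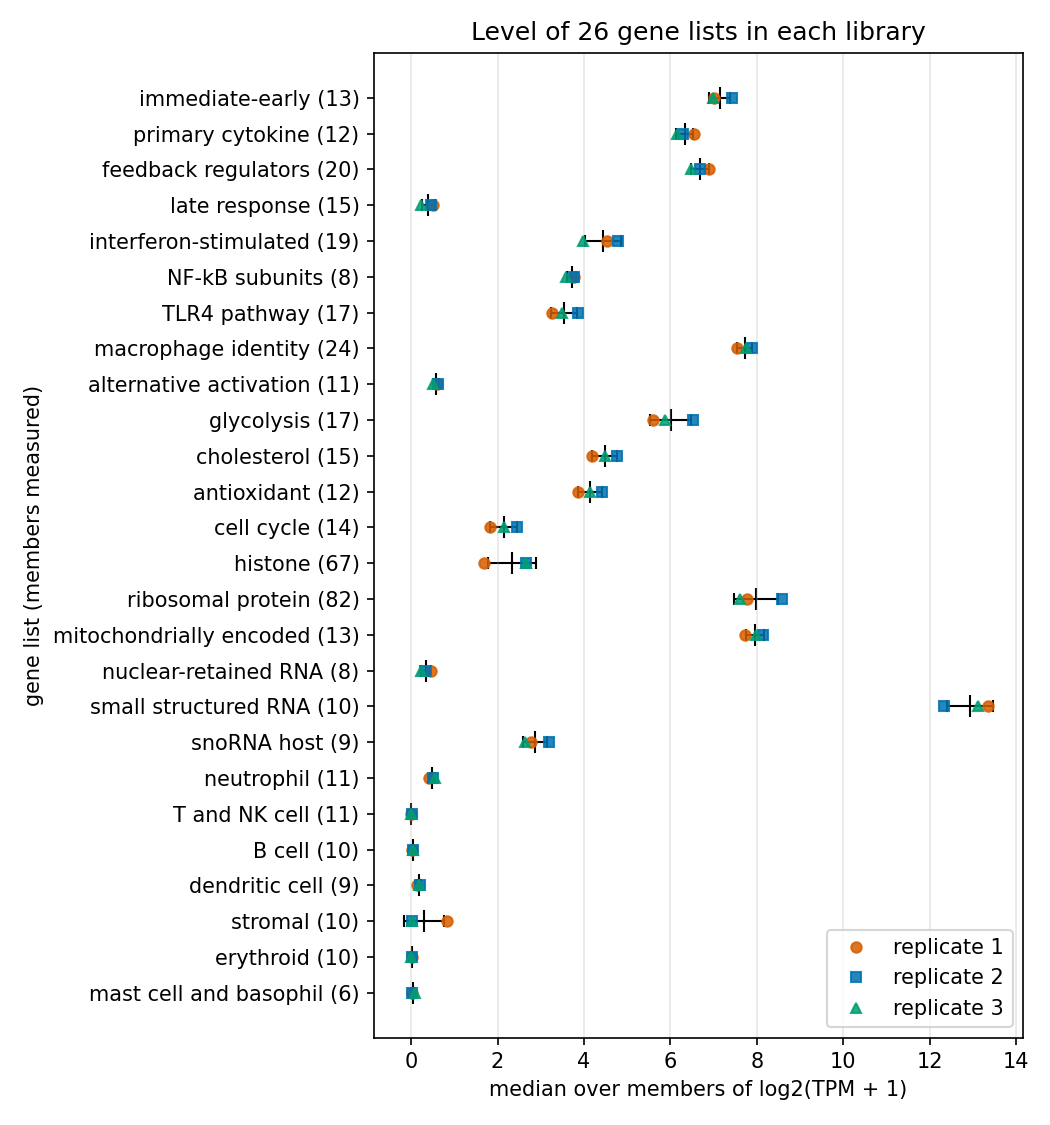
Median over members of log2(TPM + 1) (x axis) for 26 gene lists (y axis, with the number of members measured); points are the 3 libraries, and the vertical mark and bar give their mean and SD. The immediate-early list at 7.14 and the late-response list at 0.40 lie far apart, and the small structured RNA list is highest at 12.94.

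Transcripts of the receptor complex and of NF-kB itself were present at moderate levels. The TLR4 pathway list had a median of 3.53 ± 0.31, with 16 of 17 members at 1 TPM or more. Its highest members were the co-receptor gene Cd14 at 234 ± 40.0 TPM, the adaptor gene Tab2 at 27.3 ± 9.04 TPM and Tlr4 itself at 27.0 ± 3.10 TPM. All 8 genes of NF-kB and IkB kinase subunits had 1 TPM or more, with a list median of 3.71 ± 0.10, led by Rela at 22.5 ± 5.07, Nfkb1 at 18.9 ± 2.69 and Ikbkb at 17.7 ± 4.66 TPM. Each of the 24 macrophage identity genes had 10 TPM or more, with a list median of 7.73 ± 0.17. Mrc1 was counted among these macrophage genes and not among the markers of alternative activation. The listed markers of alternative activation were low, with a median of 0.57 ± 0.06 and 8 of 11 members under 1 TPM. The highest were the interleukin-4 receptor gene Il4ra at 21.04 ± 1.77 TPM, Clec10a at 12.4 ± 1.25 TPM and Chil3 at 3.48 ± 0.488 TPM.

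Among housekeeping and metabolic lists, medians were 6.00 ± 0.48 for glycolysis, 4.48 ± 0.30 for cholesterol handling, 4.14 ± 0.29 for antioxidant genes and 2.87 ± 0.29 for snoRNA host genes. The glycolytic genes Gapdh, Aldoa and Pkm had 346 ± 131, 179 ± 56.996 and 125 ± 23.5 TPM; the symbol Aldoa belongs to 2 annotated genes, and the higher is given. In the cholesterol list, the lipase gene Lpl had 253 ± 63.3, the scavenger receptor gene Cd36 115 ± 36.8 and the cholesterol exporter gene Abca1 107 ± 24.02 TPM. The peroxiredoxin gene Prdx1 had 251 ± 87.3, the autophagy receptor gene Sqstm1 217 ± 49.8 and Nfe2l2, encoding NRF2, 116 ± 27.4 TPM. The snoRNA hosts Gas5, Snhg8 and Epb41l4aos had 39.6 ± 19.2, 10.5 ± 3.51 and 10.3 ± 2.40 TPM. Cell-cycle genes had a median of 2.14 ± 0.30, and only the replication clamp gene Pcna exceeded 10 TPM, at 68.0 ± 17.2; Mcm6 had 9.08 ± 2.77 and Cdk1 6.29 ± 2.48 TPM. Replication-dependent histone genes had a median of 2.33 ± 0.56, led by Hist2h2aa2, Hist1h1c and Hist1h2bc at 48.8 ± 18.7, 44.6 ± 11.2 and 39.2 ± 10.4 TPM. Ribosomal protein genes had a median of 7.99 ± 0.52, led by Rpl41, Rps29 and Rps24 at 1130 ± 522, 761 ± 140 and 728 ± 454 TPM. Without replicate 2, Rps24 had 468 TPM, less than Rplp1 at 707 TPM, a gene chosen after its values were seen. Histone and ribosomal protein genes have near-identical copies and pseudogenes, so single-gene values in these families are uncertain. Mitochondrially encoded genes had a median of 7.95 ± 0.21, led by mt-Atp8, mt-Co1 and mt-Nd1 at 1160 ± 401, 934 ± 140 and 347 ± 81.9 TPM; mt-Atp8 overlaps its neighbour mt-Atp6. Compared with 10000 random lists of equal size drawn from genes at 1 TPM or more, the medians of 10 of the 26 lists lay in the top 2.5%.

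Medians of the marker lists of other cell types were far below that of macrophage genes, with single exceptions among the markers. Relative to the macrophage list, the median of log2(TPM + 1) differed by -7.24 ± 0.14 for neutrophils, -7.72 ± 0.17 for T and NK cells, -7.69 ± 0.16 for B cells and -7.55 ± 0.13 for dendritic cells. It differed by -7.44 ± 0.63 for stromal cells, -7.71 ± 0.18 for erythroid cells and megakaryocytes, and -7.69 ± 0.17 for mast cells and basophils. Each difference was negative in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest possible with n = 3). The medians of these lists lay near 0, from 0.005 for T and NK cells to 0.49 for neutrophils. The sizes therefore mostly restate the macrophage median of 7.73 and depend on the pseudocount. With a pseudocount of 0.1 they were -11.0 for T and NK cells, -10.7 for B cells and -9.85 for dendritic cells. Of 11 neutrophil markers, 5 had 1 TPM or more and 3 had 10 TPM or more, led by S100a9 at 17.3 ± 9.92 and Csf3r at 15.7 ± 0.819 TPM. The highest T and NK marker was the cytokine receptor gene Il7r at 33.4 ± 7.43 TPM, and the highest B-cell marker the immunoglobulin gene Ighm at 5.15 ± 2.34 TPM. Next to Il7r, the highest T and NK gene was Lck at 0.070 ± 0.113 TPM, and 0.005 TPM without replicate 2. Cd79b, Batf3, Ccr7, Ppbp, Itga2b, Prss34 and Cpa3 had 0.893 ± 0.116, 1.52 ± 0.174, 0.527 ± 0.117, 0.700 ± 0.131, 0.117 ± 0.0850, 0.0700 ± 0.0100 and 0.0667 ± 0.0404 TPM, respectively; Itga2b had 0.075 TPM without replicate 3. The T and NK and neutrophil differences depend on which members count: over members of 0.5 TPM or more they were -2.64, from Il7r alone, and -4.41.

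The stromal list stood apart in 1 library. Col1a1, encoding the alpha-1 chain of type I collagen (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042), had 2375 counts in replicate 1, 1 in replicate 2 and 14 in replicate 3. Col1a2 had 1565, 5 and 16 counts. The stromal difference from macrophage genes was -6.71 in replicate 1, -7.87 in replicate 2 and -7.73 in replicate 3, and -7.80 as the mean without replicate 1.

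Long non-coding RNAs known to stay in the nucleus were examined because the RNA came from the cytoplasm. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) nevertheless had 521 ± 246 TPM, above the macrophage list's median gene at 224 TPM. Neat1 (chromosome 19, 5824708 to 5845478) had 52.7 ± 34.3 TPM, and 34.0 TPM without replicate 3. The other 6 of 8 members had under 1 TPM, Airn being the highest of them at 0.510 ± 0.190 TPM, and the list median was 0.34 ± 0.12, against 7.73 for macrophage and 7.99 for ribosomal protein genes. Because 6 members lay near zero, that median depended on the scale and took values from -1.59 with a pseudocount of 0.1 to 5.53 over members of 0.5 TPM or more. Without a nuclear fraction, a low level cannot tell retention in the nucleus from lack of expression. Meg3 and Rian, for example, had 23 and 45 counts in replicate 1, the library with the stromal transcripts, and 0 in both other libraries. Whether those counts came from macrophages was not tested. Malat1 had 3877, 1259 and 6509 CPM in replicates 1, 2 and 3.

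The replicates differed by more than sampling noise. Over 10033 expressed genes, Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.955, 0.972 and 0.964 for replicates 1 and 2, 1 and 3, and 2 and 3. The chi-square test of counts against Poisson sampling, with Benjamini-Hochberg adjustment at 0.05, was passed by 8842 of 13237 genes with a mean count of 10 or more. Without replicate 2, the deepest library, 4334 of 13093 genes passed, in a test with less power at lower counts. The mean chi-square per gene was 125, 30.9 and 164 for the same 3 pairs of libraries, so no pair agreed within Poisson sampling noise, a comparison that covers counting error only. The common biological coefficient of variation (BCV) from edgeR was 24.98% and the median over genes 17.3%; the highest and lowest library lay within 1.5-fold of each other for 73.5% of genes.

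The 5 genes with the highest dispersion among those that passed with a mean count of 100 or more were Col3a1, Gm37376, Col5a1, Igfbp5 and H19. Col3a1, encoding type III collagen, had 1300 counts in replicate 1 and 0 in both others. The collagen gene Col5a1 had 373, 0 and 1 counts in replicates 1, 2 and 3, and Igfbp5, which encodes a growth factor-binding protein, had 299, 0 and 1. The imprinted non-coding RNA gene H19 had 577, 1 and 1 counts in replicates 1, 2 and 3. Gm37376 had 911 expected counts in replicate 2 and 0 in both others in the gene table, whereas the second transcript table gave 40.4, 73.3 and 40.5 TPM in replicates 1, 2 and 3. It lies at chromosome 19, 5801941 to 5802393, inside the Malat1 gene, so its reads cannot be told from those of Malat1 with certainty.

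Groups of genes deviated together in single libraries. Log2 CPM with a prior count was highest in replicate 1 for all 11 testable cytokine genes, although Cxcl3 without the prior count had 0.400 CPM there and 0.407 in replicate 3. Relative to the genes' own means, the cytokine median lay at 0.55 in replicate 1, -0.44 in replicate 2 and -0.11 in replicate 3. Tnf lay 0.77 above its mean in replicate 1, which is also the library with the stromal transcripts. Of the interferon-stimulated genes, 18 of 19 were highest in replicate 1, with medians of 0.33, -0.09 and -0.26 in replicates 1, 2 and 3. Of the feedback genes, 15 of 20 were highest in replicate 1, with medians of 0.32, -0.29 and -0.03 in the same order. The immediate-early list moved less, with 0.10 in replicate 1, -0.12 in replicate 2 and 0.22 in replicate 3; Fos lay at -0.42 in replicate 1. The late-response list lay at 0.27 and the NF-kB list at 0.16 in replicate 1. Histone genes lay at -0.57 in replicate 1 and 0.57 in replicate 3, with 48 of 60 highest in replicate 3. Cell-cycle genes lay at -0.28 and neutrophil markers at -0.74 in replicate 1. Of the ribosomal protein genes, 60 of 79 were highest in replicate 2, with a median of 0.23 there and -0.26 in replicate 3. Nuclear-retained RNAs lay at -1.46 and small structured RNAs at -0.69 in replicate 2. These medians describe 3 libraries and are no test of a condition.

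Measured by dispersion, 12 of 22 lists with at least 3 testable members had a median BCV in the top 2.5% of 10000 lists matched on expression. They were the immediate-early (16.6%), cytokine (25.004%), feedback (19.6%), interferon-stimulated (17.1%), macrophage (14.8%), cholesterol (14.7%), histone (40.2%), ribosomal protein (15.5%), mitochondrially encoded (14.8%), nuclear-retained (50.6%), small structured RNA (33.5%) and stromal (148%) lists. The other 10 had 41.1% (late response), 12.5% (NF-kB), 12.9% (TLR4 pathway), 26.1% (alternative activation), 12.5% (glycolysis), 13.1% (antioxidant), 20.2% (cell cycle), 27.9% (snoRNA hosts), 38.8% (neutrophil) and 42.8% (dendritic). Without replicate 1, the cytokine and interferon-stimulated lists fell to the 96.0th and 93.3rd percentile and the stromal list had too few testable members. Without replicate 2, the nuclear-retained list was at percentile 39.1, the structured RNA list at 70.5 and the cholesterol list at 93.6. Without replicate 3, the nuclear-retained, cholesterol, histone and mitochondrially encoded lists were at 67.7, 51.4, 92.6 and 32.0. Other lists entered the top 2.5%: the cell-cycle and neutrophil lists without replicate 2, at 98.8 and 99.0, and with DESeq2 gene-wise dispersions, at 99.6 and 99.5. Over genes with a mean count of 100 or more, the neutrophil and late-response lists did so, at 99.8 and 99.9.

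**Figure D3:**
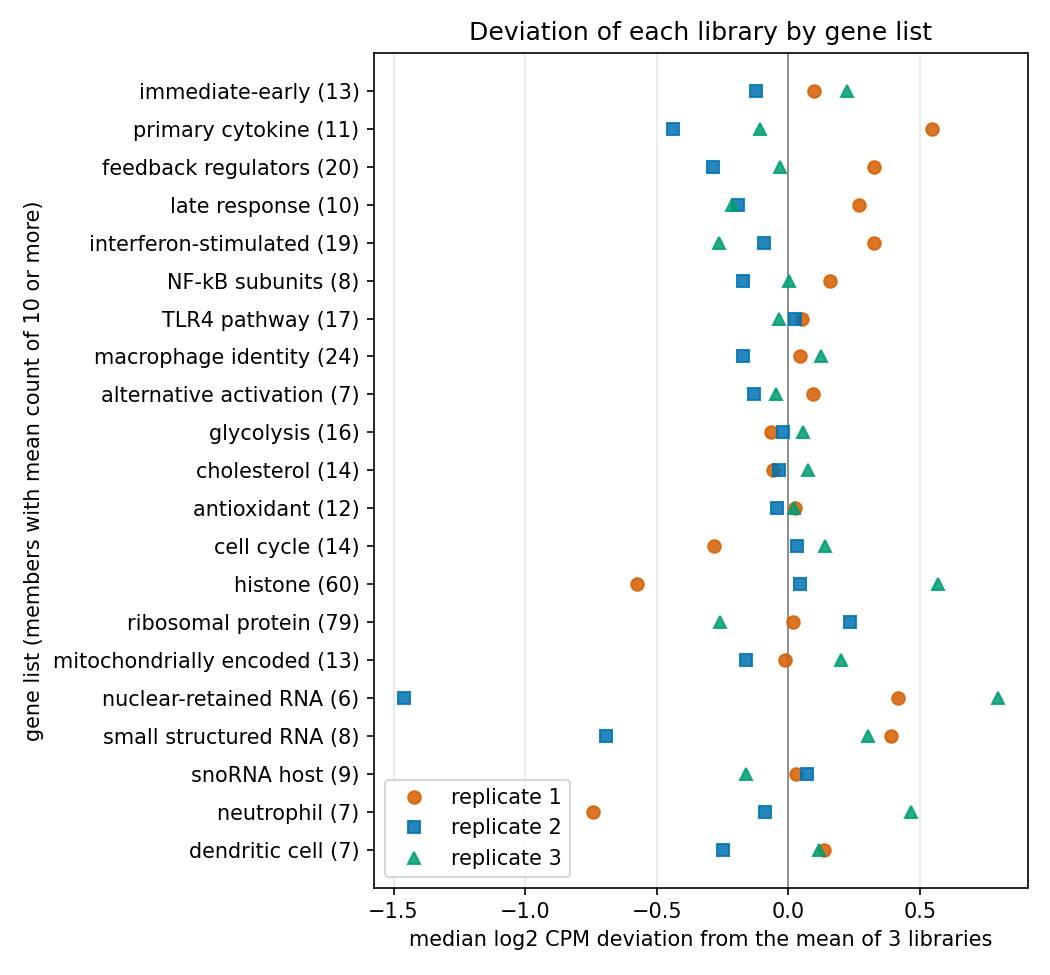
Median log2 CPM deviation of each library from the genes' means over the 3 libraries (x axis) for 21 gene lists (y axis, with the number of members of mean count 10 or more); points are libraries, and the stromal list, at 4.73 in replicate 1, is left out. The cytokine list lies at 0.55 in replicate 1 and the nuclear-retained list at -1.46 in replicate 2.

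Leading transcripts were compared for the named response genes. Of 19 named response genes, the leading transcript was annotated as protein-coding in 18 and held at least 50% of the gene's TPM in 17; for 4 of these, Ccl3, Il10, Ebi3 and Ifit3, 1 transcript is annotated, which fixes the share. Tnf-201 held 100% of its gene, Egr1-202 90.5 ± 1.56% and Fos-201 70.5 ± 11.6%. Zfp36-201 held 59.7 ± 15.7%. Myc-202 was below 50%, at 26.4 ± 5.41%. Myc was also the single gene whose leader differed in the second transcript table. The leading transcript of Mx2, an antiviral gene, was annotated as a polymorphic pseudogene and held 88.2 ± 8.05%. Transcripts annotated as retained intron held 3.32 ± 0.18% of the TPM of expressed protein-coding genes. The share was 0.454 ± 0.143% in the immediate-early, 2.11 ± 1.09% in the cytokine, 1.69 ± 0.689% in the feedback, 5.08 ± 1.63% in the NF-kB and 10.7 ± 1.76% in the TLR4 pathway list. These shares depended on the table: the second one gave 0.886 ± 0.184%, 2.44 ± 1.35%, 2.72 ± 1.13%, 9.87 ± 1.28% and 13.5 ± 1.88% for the same lists in that order.

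The 2 transcript-level tables of each library gave similar gene-level values for messenger RNAs and different totals. Across protein-coding genes rescaled to their own sum, Pearson correlations of log2(TPM + 1) between the tables were 0.981, 0.983 and 0.981 in replicates 1, 2 and 3; across all genes at 1 TPM or more in either table of the library, they were 0.885, 0.896 and 0.881. The 3 named genes that differed most were Gm12896 and Gm12895, processed pseudogenes of 226 nt on chromosome 4 (122122847 to 122123072 and 122455210 to 122455435), and Gm23935, annotated as a microRNA gene of 57 nt on chromosome 16 (11144125 to 11144181). Gm12896 had 177833 ± 68525 TPM in the second table and 0 counts in the first. In the second table, Gm12895 and Gm12896 had equal estimated counts in replicates 2 and 3, at 993704 and 4897460. Gm23935 had the same counts in each library as the microRNA entries Gm24245 and Gm24270. The division of reads within each set is therefore uncertain. Of all genes, 118 had 1 TPM or more in the first table and under 0.1 in the second, 13 of them protein-coding, and 272 the opposite, 10 of them protein-coding.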

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

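Counts on the phiX174 row, a bacteriophage genome often added to sequencing runs as a control, belong to no comparison. They lay above the 3 counts that a count of 0 allows in each library. The row held 108582 counts in replicate 1, 55077 in replicate 2 and 34722 in replicate 3. As shares of all counts these are 0.462% (95% Wilson interval 0.459% to 0.465%), 0.109% (0.108% to 0.110%) and 0.0969% (0.0959% to 0.0980%). No explanation was tested for the higher share in replicate 1. Groups of 3 libraries were too small for the outlier test used for larger groups.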

How the results depend on the processing

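The TPM scale relative to nuclear protein-coding genes was chosen after seeing the data. All 6 early-late and 7 other-cell differences kept their sign under the alternatives run, and 17 of 19 response genes had a leading transcript of 50% or more under each, 4 of them with 1 annotated transcript. The filter at 0.5 TPM left no mast cell or basophil member and gave no value for that list. Early lists lay 3.89 to 8.44 above the late-response list and 0.61 to 2.82 above the interferon-stimulated list. Expressed genes numbered 10033, 8779 to 12057 under other scalings, tables and a threshold of 0.5 TPM, and 6321 at a threshold of 5 TPM. The nuclear-retained median of 0.34 became -1.59 with a pseudocount of 0.1, 5.53 over members of 0.5 TPM or more, 2.00 as a mean, 0.90 in TMM-scaled CPM and 0.98 relative to protein-coding genes. These shifts follow from members near zero and from the change of scale. Genes varying beyond sampling noise numbered 8842 of 13237 tested. They numbered 10064 of 21855 without the filter on low counts and 7449 of 10065 at a mean count of 100 or more. In the second transcript table they numbered 10872 of 15513. The range was 7449 to 10872 under other scalings, filters and tables, and 4334 to 7376 with 1 library left out, the lowest without replicate 2. A test over 2 libraries has less power, and its power depends on counts, of which the fewest remain without replicate 2. The numbers with 1 library left out therefore do not by themselves set replicate 2 apart. The common BCV, as a fraction, was 0.186 without replicate 2, against 0.241 without replicate 1 and 0.296 without replicate 3. By this measure replicate 2 differed most from the others. It is also the deepest library, and the cause was not tested. The number of highly dispersed lists was 12, 12 to 14 with DESeq2 or higher counts, and 8 to 11 with 1 library left out. The number of lists at the top of the level distribution was 10 to 12. Over the alternatives that keep all libraries, list levels moved by more than 1 SD in 100 recalculations and by less in 74, and TPM of named genes in 165 and 108. A mean over 3 libraries cannot move by 1 SD when 1 is left out, so that measure says nothing of single libraries. Leaving out a library changed which genes were the highest named members in 8 of 26 lists. No paired analysis was possible because there is one group. Depth limits statements on genes near 0.1 CPM, such as Il12a, and 3 libraries limit every sign-flip permutation p to 0.25 or more.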

Other observations

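The gene lists in this part and the tests of library size, of the stromal level against Tnf and of the late-response list were chosen after results were seen, except that the 25 mesenchymal genes were fixed before their own values were examined. Genes named here lie outside the rule for named genes and were chosen after their values were seen, apart from Col1a1, Col1a2, H19, Tnf, Malat1, Neat1 and the 3 pseudogene and microRNA entries named above. Genes of lipid-laden and tissue-remodelling macrophages were among the most abundant: 9 of 12 had 100 TPM or more, with a list median of 8.34 ± 0.35 log2(TPM + 1). The galectin gene Lgals3 had 1501 ± 460 TPM, the fatty acid-binding protein gene Fabp5 1281 ± 521 TPM, the osteopontin gene Spp1 980 ± 336 TPM and the lipid droplet gene Plin2 409 ± 110 TPM. The bone protease gene Ctsk was low at 1.18 ± 0.131 TPM. Chemokine and complement receptors were uneven: C3ar1 and C5ar1, receptors of complement peptides, had 189 ± 22.3 and 102 ± 14.3 TPM and Cxcr4 39.2 ± 7.06 TPM, while 3 of 10, Cx3cr1, Fpr1 and Fpr2, had under 1 TPM. The list median was 2.42 ± 0.08.

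All 12 inflammasome genes had 1 TPM or more, with a list median of 4.15 ± 0.10. Txnip, encoding a thioredoxin-binding protein, had 54.4 ± 19.01 TPM, the protease gene Casp1 29.01 ± 8.63, the sensor genes Nlrp3 22.7 ± 4.1953 and Aim2 21.01 ± 7.09, and the pore-forming protein gene Gsdmd 15.5 ± 2.71 TPM. Of 14 other pattern-recognition receptor genes, 13 had 1 TPM or more, with a median of 3.54 ± 0.13. The beta-glucan receptor gene Clec7a had 162 ± 39.2 TPM, and the endosomal receptor genes Tlr13, Tlr7 and Tlr8 had 70.5 ± 11.6, 63.5 ± 14.7 and 52.5 ± 11.1 TPM. The bacterial lipoprotein receptor gene Tlr2 had 43.9 ± 7.57 TPM and the flagellin receptor gene Tlr5 0.840 ± 0.182 TPM.

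Replicate 1 held mesenchymal and imprinted transcripts that were nearly missing from both other libraries. A difference in depth does not account for this: at the replicate 1 rate, the deepest library, replicate 2, would hold 5736 counts of Col1a1, and it held 1, with an upper 95% limit of 5.57. RNA or reads from another tissue in replicate 1 may be the source, judged on 25 further mesenchymal genes not examined before. These summed to 12.8 times the CPM of the higher other library, and all 25 were highest in replicate 1. In contrast, 14 epithelial, liver, neural and muscle genes summed to 1.07 times. That ratio rests on 7, 15 and 10 counts in replicates 1, 2 and 3, so these genes were near the floor in each library. Of the 25, only Efemp2 reached 1 TPM without replicate 1; the most abundant genes of the signal were Col1a1 at 8.94, Col1a2 at 6.59, H19 at 6.01 and Igf2 at 5.98 TPM in replicate 1, and 7 imprinted genes summed to 69.8 CPM there against 0.269 and 0.196. Whether cells in the culture, carried-over RNA or reads of another library brought them was not tested, and the design gives no biological explanation to test.

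Relative to both other libraries, replicate 1 was higher in cytokine genes than in immediate-early genes. The cytokine list was also low in replicate 2: corrected for GC content and length, it lay at 0.56, -0.56 and -0.02 in replicates 1, 2 and 3. Its difference between replicate 1 and the mean of the others therefore also holds the low level of replicate 2. GC content and length do not account for the gap between these 2 lists as a whole. It was 0.67 before and 0.69 (95% bootstrap interval 0.42 to 1.09) after removing the trend with GC content and length, which was weak (r2 = 0.0185). The bootstrap redrew list members, so its intervals here and below measure spread between genes and not between libraries. RNA from another tissue stays open, because the cytokine content of such a tissue was not measured. The highest stromal transcript of replicate 1 reached 3.66% of its Tnf excess of 244.5 TPM. An excess over 10 times that transcript was seen in 2 of 11 cytokine genes. Low genes could not reach that bar, such as Cxcl3 at 0.17 TPM in replicate 1, so this count cannot decide the question. These excesses are in TPM as deposited, of which nuclear protein-coding genes held 22.3% in replicate 1 but 34.4% and 24.3% in replicates 2 and 3. That scale understates an excess in replicate 1, and the genes were not counted on another scale. That replicate 1 was further along the response stays open too: 10 late-response genes had a median of 0.40 (log2) above the other libraries, which restates a deviation seen before the test was chosen, and the corrected deviation of this list in replicate 1, 0.32, had an interval of -0.10 to 0.85. The labels give the same time for all 3 libraries, other differences in handling stay open, and no biological explanation was tested.

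Before any correction, the list of ribosomal protein genes was highest in replicate 2. GC content and length account for part of this at most: the list's median deviation was 0.21 (95% bootstrap interval 0.18 to 0.26) before and 0.12 (0.09 to 0.20) after removing their trend, which had r2 = 0.125 over 9619 other genes. The corrected interval, taken over genes and not libraries, leaves out 0 but includes values below 50% of the first. The size of the remaining part is therefore uncertain. After the same correction the list lay at 0.08 (0.03 to 0.12) in replicate 1 and -0.22 (-0.23 to -0.20) in replicate 3. The largest of these corrected deviations is the low level in replicate 3. The intervals of replicates 1 and 2 overlap, but they rest on the same genes, so their overlap is no test of the difference. Uncorrected, 60 of 79 genes were highest in replicate 2 and 19 in replicate 1. Differences within genes were not computed after the correction, so whether replicate 2 stays above replicate 1 was not tested. No other technical and no biological explanation was tested.

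Genes of the Y chromosome, 4 in the list, summed to 27 counts in replicate 1 and 0 in each other library in the gene table, but to 59.6, 37.5 and 67.8 estimated counts in replicates 1, 2 and 3 in the second transcript table, and Xist had 2555, 1490 and 7290 counts in replicates 1, 2 and 3. Neat1 deviated by 0.65, -1.59 and 0.94 (log2 CPM) in replicates 1, 2 and 3, in the same order as Malat1 at 0.29, -1.33 and 1.04. In the second transcript table, 5 short entries, Gm12895, Gm12896, Gm23935, Gm24245 and Gm24270, held 66.0%, 46.9% and 79.8% of the TPM in replicates 1, 2 and 3, while nuclear protein-coding genes held 8.83%, 21.4% and 5.91%.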
